A study of Drosophila melanogaster with 96 samples.

How the data were processed

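The series holds stranded mRNA sequencing of fly heads, with 96 libraries in 4 groups of 24: female control, female Achl RNAi, male control and male Achl RNAi. Per the labels' protocols, flies were moved from a light-dark cycle to constant darkness before collection, and 1 library per group was made every 2 h from circadian time (CT) 24 to CT70. The control construct is not stated in the labels. The authors aligned reads with STAR and quantified genes with RSEM on dm6, per the submitters' processing notes, and versions of these are not given in the sources used here. The deposited values are TPM, a measure scaled to the same sum in each library, with 1 value per gene and library, and the sum of every library was 1000000 within 0.79. Sequencing depth per library is unknown, since TPM carry no counts, so no counting interval is given and the precision of each value is read only from the spread between libraries.

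Among the 17698 deposited genes, 1179 were at 0 in every library and 17560 had an identifier in the annotation (Ensembl release 115, assembly BDGP6, which is dm6). Positions come from that annotation. The test kept the 10568 genes with at least 1 TPM in at least 24 libraries, and took log2 of TPM plus a pseudocount of 1. Among them were 9666 protein-coding genes, 551 ncRNAs, 151 snoRNAs and 85 pseudogenes, and 86 genes were not in the annotation. A set of 116 tested genes had values identical to another gene in every library, so which of those genes the reads came from is uncertain. Correlations between libraries lay between 0.8327 and 0.9884, and 0 pairs of libraries were identical.

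All 96 libraries were fitted together with limma 3.58.1 (trend and robust options in R 4.3.3). The model had a mean, a cosine and a sine of period 24 h for each group. Level comparisons were contrasts of the group means, and the rhythm of a group was an F test of its cosine and sine. A change of rhythm was an F test that the cosine and sine differed between groups. P-values were two-sided for contrasts and adjusted by Benjamini-Hochberg over the tested genes, with a threshold of 0.05. Peak-to-trough ratio and peak time came from the fitted coefficients, with standard errors by the delta method. The level of Achl was also compared by flipping the signs of the 24 same-CT differences at random, two-sided. Each CT has 1 library per group, so the p-values measure only the spread of these libraries around the fitted courses. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

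The comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. That rule takes Achl and the 17 core clock genes. It then takes, for RNAi in each sex and for sex in controls, the 10 genes of largest fold change in each direction among called genes with the fitted direction in at least 20 of 24 same-CT pairs and a mean of at least 5 TPM in the higher group. It adds the 6 genes of lowest p in the interaction, in the rhythm of each group and in each rhythm comparison, and, as leading members, those of lowest p in each list described. The design planned a count-based test for counts, which was not used because the values are TPM. Gene lists were tested with camera at a correlation of 0.01 and with an estimated correlation, adjusted over the lists, and their members were counted over all genes and adjusted over the list alone. Camera compares the members of a list with all other tested genes, so a list that fell less than the others points up. The lists were core clock, clock-controlled head outputs, Imd, Toll, JAK-STAT and Turandot, antiviral RNAi, heat shock, photoreceptor, neuron, glia, fat body, yolk and female fat body, muscle, hemocyte, gut, ovary, male reproductive, sex determination and dosage compensation, Y-linked, olfactory, detoxification, insulin and starvation, neuropeptide, transgene marker, cytosolic ribosomal protein, mitochondrially encoded, nuclear OXPHOS, proteasome, cuticle and histone genes. The ovary list had 1 tested gene of 19, the male reproductive list 2 of 20 and the Y-linked list 0 of 12, so these were not tested as lists. Clock outputs include Achl itself, and trpl is in that list and in the photoreceptor list.

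The tests were tested on simulated data, drawn from the means and residual spreads of the tested genes, in which 66 or 67 genes per size, from those of higher level, were given a change. A log2 change of 0.5 was recovered in 94.0% of genes for RNAi in females, 95.5% in males, 85.1% for the interaction and 94.0% for sex. A rhythm with a ratio of 1.5 was recovered in 58.2% of genes in female controls, 61.2% in female RNAi, 64.2% in male controls and 71.6% in male RNAi. When 1 group only was given a rhythm of that ratio, the difference was recovered in 31.3% of genes in females, 22.4% in males and 38.8% between sexes, and shifts of peak time were not simulated. False calls numbered from 0 to 20 per test among 10568 genes. The simulated spread of a gene was the same in all 4 groups, so the shares recovered do not compare the power of the groups. It was also independent between genes and libraries. False calls from a structure that many genes share, as in the random orders described at the end, are therefore not covered.

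Alternatives covered limma without trend and robust options, per-library median centring, no filter on low values, a filter at 5 TPM, a pseudocount of 0.1, each day alone, a linear time trend, a 12 h harmonic, the groups compared alone, CT as a block, a rank test of rhythm, stricter rhythm thresholds and periods of 20 h and 28 h. After the data were seen, alternatives were added for a split of female libraries by the mitochondrial transcript mt:lrRNA at 50000 TPM, for rescaling over nuclear protein-coding genes, for centring together with that split, for leaving out 5 first-day female libraries, for gene list tests on centred values, for clock outputs without Achl and for the comparison of effects between sexes on centred values. For ninaE, 2 tests of explanations had also been computed after the result was seen, and its values are given in the report without a weighing of explanations. No library was left out of the main test.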

Results

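Heads of adult flies were profiled by RNA sequencing over 2 days of constant darkness, in females and males that carried RNAi against Achl or a control construct that the labels do not describe. Each of the 4 groups held 24 libraries, each made from a pool of heads, 1 every 2 h from CT24 to CT70. There were no replicates at a time point, so the errors below are spreads over the 24 libraries of a group (SD, n = 24) or standard errors (SE) of the fitted change. Values are TPM as deposited, and depth is unknown. Female libraries fell into sets by mt:lrRNA, a mitochondrial ribosomal RNA: 14 control and 15 RNAi libraries had less than 50000 TPM, and 12 of each were from the second day (CT48 to CT70). No male library was below that level. Median mt:lrRNA was 27652 TPM in female controls, 26207 in female RNAi, 117697 in male controls and 118520 in male RNAi. Values within the female sets, called low-mt and high-mt libraries, are given beside pooled ones for part of the genes.

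The first question was whether RNAi lowered its target. Achl (FBgn0033936, chromosome 2R, 14420324 to 14424764 on dm6) had 68.3 ± 21.8 TPM in female controls and 15.6 ± 2.95 in female RNAi heads, which is 22.8% of control. In males it had 77.7 ± 39.1 TPM in controls and 22.5 ± 7.65 in RNAi heads, 28.9% of control. Achl fell by 2.01 (SE 0.10) on the log2 scale in females, adjusted p = 3.5e-31, and by 1.63 in males, adjusted p = 1.9e-25. It was lower in RNAi in 24 of 24 same-CT pairs in each sex, permutation p = 1e-05, the smallest that the permutations can give. Relative to the median gene its log2 change was -1.84 in females and -1.47 in males. The rhythm of Achl itself had a peak-to-trough ratio of 2.20 with a peak at CT17.0 in female controls and 3.78 at CT16.1 in male controls. In RNAi heads the ratio was 1.47 in females, where the rhythm did not pass the test (adjusted p = 0.369), and 2.29 in males. The difference in rhythm did not pass in either sex, adjusted p = 0.422 in females and 0.968 in males.

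**Figure D1:**
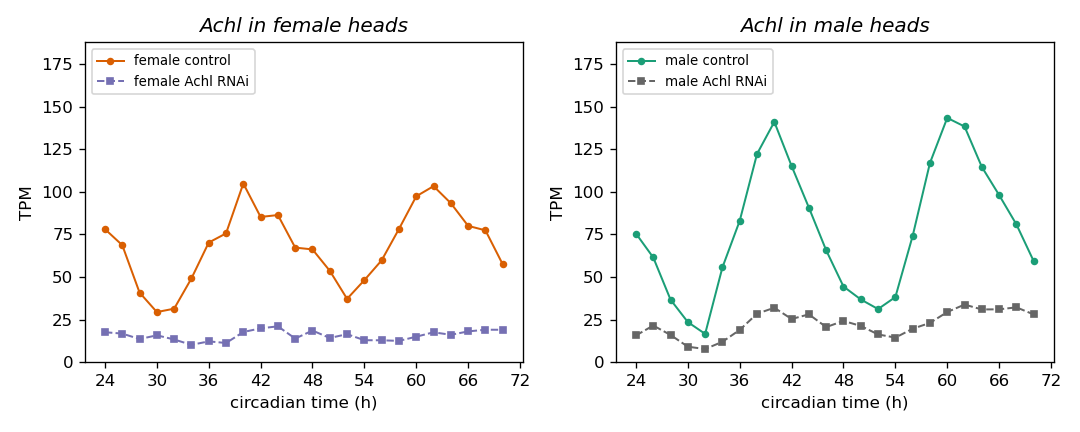
TPM of Achl against circadian time in hours, in female (left) and male (right) heads, each point 1 library of control (circles) or Achl RNAi (squares). Means were 68.3 and 15.6 TPM in females and 77.7 and 22.5 TPM in males.

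The next comparison asked which genes changed with Achl RNAi in female heads. Antimicrobial peptide genes rose most. Dro, which encodes drosocin, went from 52.9 ± 197 to 1670 ± 1145 TPM, a log2 change of 7.33 (SE 0.41, adjusted p = 2.2e-28), and DptA, which encodes diptericin, from 200 ± 689 to 3559 ± 2517 TPM, 7.09 (SE 0.53). SPH93, a serine protease homolog, went from 1.12 ± 0.863 to 409 ± 450 TPM, a log2 change of 6.88. The rhodopsin gene ninaE fell from 33790 ± 6562 to 12210 ± 2070 TPM, a log2 change of -1.46 (SE 0.07, adjusted p = 6.3e-34), and was lower in 24 of 24 pairs. Among the other genes with the largest rise were DptB (6.59), CecA1 (6.76), AttC (6.56), Mtk (6.32) and IM18 (7.07), with the ncRNAs CR44404 (7.26) and CR45045 (6.96). DptA and IM18 were higher in 23 of 24 pairs and the other 8 genes in 24. The control mean of the peptides rests on few libraries: median DptA was 9.55 TPM in female controls and 3188 in female RNAi, and 1 control library, at CT56, had 3335 TPM.

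Besides Achl and ninaE, the genes of largest fall in females were the neuropeptide gene CNMa (-1.36, from 26.3 to 9.92 TPM), the cuticle protein gene Cpr51A (-1.35), CG9377 (-1.25), CG5160 (-1.22), CG33926 (-1.21), CG11200 (-1.20), CG8654 (-1.20) and Pepck (-1.19), the gluconeogenesis enzyme, from 517 ± 180 to 239 ± 109 TPM. Cpr51A lies on chromosome 2R at 14512559 to 14515211, on the same arm as Achl, and its log2 change was -0.88 in high-mt and -1.65 in low-mt libraries. For ninaE these values were -1.38 and -1.54, for Dro 7.71 and 7.11, for DptA 7.63 and 6.72, for CecA1 7.42 and 6.33, for CR45045 7.43 and 6.73, for DptB 6.96 and 6.32 and for Pepck -1.46 and -1.05. With centred values ninaE had a log2 change of -1.29 (SE 0.05) in females, while the other 24 photoreceptor genes had a median of -0.08 (SD 0.29).

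Gene lists moved as follows in females. The Imd list, an antibacterial signalling pathway and its peptides, had 20 members higher and 5 lower of 25 (the same 20 and 5 adjusted over the list alone), median log2 change 2.97, adjusted p = 1.9e-48. Its call held with an estimated correlation (adjusted p = 1.9e-05), and AttA rose by 6.29 and PGRP-SD, a recognition protein gene, by 2.97. The Toll list had 21 higher and 3 lower of 28 (22 and 3 adjusted over the list alone), median 1.59, adjusted p = 6.1e-59, and 2.5e-06 with an estimated correlation. In it IM1 rose by 4.07 (326 to 6334 TPM), IM23 by 6.12 and IM2 by 3.26. Mitochondrially encoded genes had 8 higher and 1 lower of 22 (8 and 1 adjusted over the list alone), adjusted p = 6.6e-10, and adjusted p = 0.293 with an estimated correlation. In that list mt:ND4L rose by 3.14, but by 7.05 in high-mt and 0.57 in low-mt libraries, and mt:ND6 by 2.55, with 6.07 and 0.25. Glia markers had 1 higher and 15 lower of 18 (1 and 15 adjusted over the list alone), adjusted p = 0.00554, and adjusted p = 0.48 with an estimated correlation, with Eaat1, a glutamate transporter gene, at -0.39 and CG6126 at -0.61. Photoreceptor markers had 0 higher and 19 lower of 25 (0 and 19 adjusted over the list alone), adjusted p = 0.0179, and adjusted p = 0.702 with an estimated correlation, with trpl, a light-activated channel gene, at -1.07 and ort, a histamine receptor gene, at -0.42. Hemocyte markers had 3 higher and 2 lower of 13 (2 and 2 adjusted over the list alone), adjusted p = 0.00466, and adjusted p = 0.48 with an estimated correlation, with eater at 0.39, srp at -0.22 and NimC1 at 0.31.

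The remaining lists did not pass the list test in females as deposited. As background to their counts, 497 of all 10568 tested genes were called higher and 5885 lower in females. Clock-controlled head outputs had 1 member higher and 15 lower of 23 (1 and 16 adjusted over the list alone), median -0.34, adjusted p = 0.0561. Relative to the median gene, 3 were higher and 11 lower, median -0.17, and the list then passed (adjusted p = 6.3e-04, and 0.00846 with an estimated correlation). Without Achl, the target itself, that call held (adjusted p = 0.00675) but was lost with an estimated correlation (adjusted p = 0.0791). In it trpl, Achl and to, the takeout gene, were lower (to at -0.60), and Cyp4d21, a cytochrome P450 gene, was higher (1.04). Core clock genes had 0 higher and 10 lower of 17 (0 and 11 adjusted over the list alone), with Pdf, the clock neuron peptide gene, at -0.35 and its receptor gene Pdfr at -0.32. Called members, higher then lower, numbered 2 and 3 of 9 for JAK-STAT and Turandot, 0 and 6 of 8 for antiviral RNAi, 3 and 8 of 16 for heat shock, 0 and 21 of 28 for neuron, 2 and 8 of 14 for fat body, 2 and 3 of 7 for yolk and 0 and 12 of 22 for muscle genes. They numbered 1 and 0 of 6 for gut, 0 and 13 of 15 for sex determination, 0 and 12 of 28 for olfactory, 4 and 19 of 38 for detoxification, 1 and 11 of 20 for insulin and starvation, 0 and 14 of 28 for neuropeptide and 0 and 1 of 4 for transgene marker genes. Ribosomal proteins had 1 and 40 of 85, OXPHOS 0 and 24 of 67, proteasome 0 and 9 of 31, cuticle 1 and 16 of 32 and histone genes 0 and 3 of 4. Adjusted over the list alone, counts differed for JAK-STAT (3 and 3), neuron (0 and 22), sex determination (0 and 14), ribosomal protein (1 and 35), OXPHOS (0 and 19) and proteasome genes (0 and 8). Median, mean and test differed in sign for the heat shock list (median -0.17, mean -0.02, test up), JAK-STAT (-0.04, 0.29, up), yolk (-0.19, 0.05, up) and gut (-0.05, 0.17, up). For the fat body, olfactory, detoxification, OXPHOS, proteasome, cuticle and transgene lists median and mean were negative while the test pointed up. Its direction is relative to the other tested genes, most of which were lower, and does not mean a rise in level. Single genes of these lists moved apart: in the detoxification list Cyp6a17 rose by 2.79 (6.30 to 49.3 TPM) while Cyp4ac2 (-1.10) and Cyp6a8 (-1.11) fell, and Hsp22 rose (0.84 in high-mt and 1.95 in low-mt libraries) while Hsf, the heat shock factor gene, had -0.23. In the fat body list AkhR, the adipokinetic hormone receptor gene, fell by 0.77.

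By the limma test 6382 of 10568 genes passed in females, 497 higher and 5885 lower, with 106 at least 2-fold higher and 32 at least 2-fold lower. The median log2 change of all genes was -0.18, and after per-library median centring 2351 genes passed, 1188 higher and 1163 lower. Within high-mt libraries 5137 genes passed (607 higher, 4530 lower), and within low-mt libraries 5800 (401 higher, 5399 lower). The share in each direction thus rests on the scaling.

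**Figure D2:**
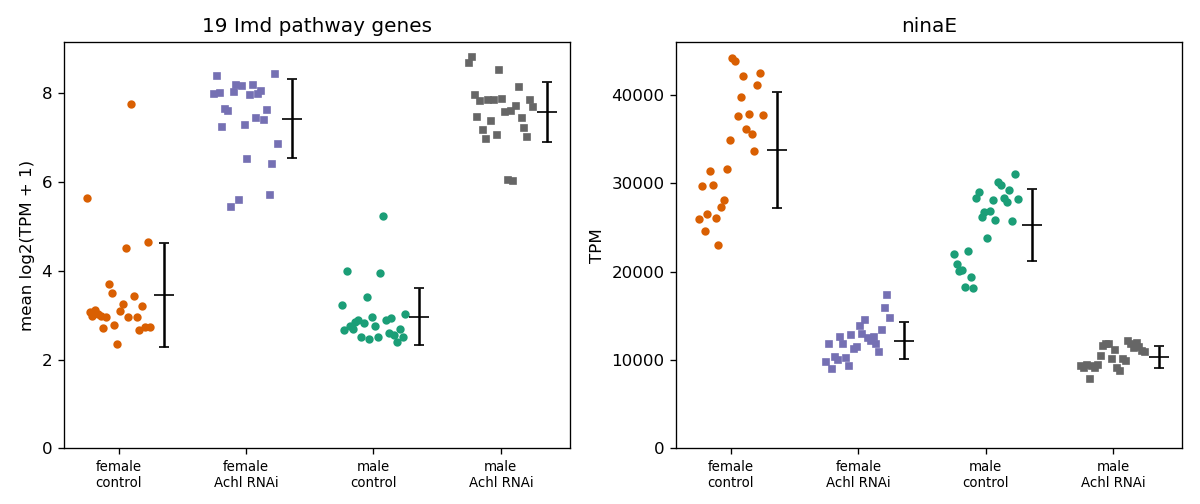
Mean log2(TPM + 1) of the 19 Imd list genes called higher with RNAi in both sexes (left) and TPM of ninaE (right) in each library (points, in order of circadian time within a group), with the group mean and SD beside them. The Imd mean was 7.42 in female RNAi and 3.45 in female controls, and ninaE did not overlap between RNAi (8991 to 17379 TPM in females) and control (23028 to 44131 TPM).

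The same question was asked of male heads. SPH93 rose from 0.248 ± 0.547 to 917 ± 444 TPM, a log2 change of 9.43 (SE 0.26, adjusted p = 9.9e-50), and DptA from 28.7 ± 91.0 to 2768 ± 2048 TPM, 9.16 (SE 0.53, adjusted p = 1.4e-27). Genes that fell most were Lsp2, a larval serum storage protein gene, from 538 ± 152 to 64.9 ± 85.8 TPM (-3.95, SE 0.55), and Obp99b, an odorant binding protein gene, from 144 ± 75.2 to 16.2 ± 13.6 TPM (-3.49, SE 0.27). The 10 genes of largest change in each direction kept it in 24 of 24 pairs. The other genes of largest rise were DptB (8.57), CR44404 (8.77), CecA1 (8.51), CR45045 (8.40), Dro (8.28), AttC (7.88), CecA2 (7.67) and Mtk (7.54). CG16926 fell from 586 to 65.8 TPM (-3.47), CG16995 from 6.58 to 0.203 TPM (-2.64), tobi, a glucosidase gene, from 146 to 37.1 TPM (-2.37), CG33926 by 2.27, squ by 2.01 and CG10621 by 1.79. Pepck fell from 609 ± 117 to 190 ± 83.5 TPM (-1.79), and CG45087 carried the same values as Pepck in every library. ninaE fell from 25265 ± 4084 to 10381 ± 1233 TPM, a log2 change of -1.27, and -1.11 relative to the median gene.

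In males the Imd list had 19 members higher and 2 lower of 25 (19 and 3 adjusted over the list alone), median 2.33, adjusted p = 9.9e-50, and 1.4e-05 with an estimated correlation. Dro, AttA (6.60) and CecA1 were among its members of lowest p, while DptA and DptB changed more than AttA. The Toll list had 23 higher and 2 lower of 28 (23 and 3 adjusted over the list alone), median 1.31, adjusted p = 1.2e-57, and 3.3e-06 with an estimated correlation, with IM23 (6.34), IM1 (4.03) and Drs, which encodes drosomycin (7.52). Olfactory genes had 0 higher and 26 lower of 28 (0 and 27 adjusted over the list alone), median -0.47, adjusted p = 8.2e-06, and adjusted p = 0.37 with an estimated correlation. After centring 20 of 28 were lower and that call held with an estimated correlation, adjusted p = 0.00551. Obp56d (-1.06), a5 (-0.62) and Est-6, an esterase gene (-0.46), followed Obp99b. Detoxification genes had 1 higher and 29 lower of 38 (1 and 30 adjusted over the list alone), adjusted p = 1.3e-05, and adjusted p = 0.46 with an estimated correlation. After centring 3 were higher and 22 lower, and that call also held, adjusted p = 0.0328. Cyp6a17 rose by 2.23 while Cyp28d1 (-1.27) and Ugt86Dd (-0.79) fell. Clock outputs had 0 higher and 17 lower of 23 (0 and 17 adjusted over the list alone), median -0.32, adjusted p = 4.1e-04, and adjusted p = 0.46 with an estimated correlation. With centred values 2 were higher and 12 lower, adjusted p = 9.3e-04 with an estimated correlation, and without Achl adjusted p = 0.00740 with an estimated correlation. After Achl the leading members were to (-0.83), trpl (813 to 408 TPM) and Cyp6a21 (-0.73).

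Most tested ribosomal protein, OXPHOS and fat body genes were called lower in males. Each of these lists passed the list test but lost its call with an estimated correlation. Ribosomal proteins had 82 of 85 lower (82 adjusted over the list alone), median -0.51, adjusted p = 2.6e-05, and adjusted p = 0.678 with an estimated correlation, with RpS27 at -0.39 and RpL37A at -0.38. OXPHOS genes had 59 of 67 lower (59 adjusted over the list alone), adjusted p = 4.1e-04, and adjusted p = 0.678 with an estimated correlation, with ND-15 at -0.43 and ND-B14.5A at -0.44. On centred values 70 ribosomal protein genes and 40 OXPHOS genes were lower. Fat body markers had 11 of 14 lower (11 adjusted over the list alone), median -0.54, adjusted p = 0.00311, and adjusted p = 0.37 with an estimated correlation, led by Pepck, mdy, a triglyceride synthesis gene (-0.57), and CG9914 (-1.66). Mitochondrially encoded genes had 9 higher and 0 lower of 22 (8 and 0 adjusted over the list alone), adjusted p = 6.2e-07, and adjusted p = 0.37 with an estimated correlation, with mt:ND4 at 0.93 and mt:ND3 at 0.96. Photoreceptor markers had 18 of 25 lower (18 adjusted over the list alone), adjusted p = 0.0353, and adjusted p = 0.678 with an estimated correlation, and glia markers 15 of 18 lower (15 adjusted over the list alone), adjusted p = 0.00235, and adjusted p = 0.37 with an estimated correlation, with Indy, a citrate transporter gene, at -0.48 and Inx2, a gap junction gene, at -0.29.

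In males 487 of all 10568 tested genes were called higher and 5657 lower, with a median log2 change of -0.16. Against that background, lists that did not pass in males had these called members, higher then lower. There were 0 and 9 of 17 core clock, 0 and 5 of 9 JAK-STAT, 0 and 7 of 8 antiviral RNAi, 3 and 7 of 16 heat shock, 0 and 8 of 28 neuron, 0 and 3 of 7 yolk, 0 and 7 of 22 muscle, 0 and 5 of 13 hemocyte and 2 and 3 of 6 gut genes. There were 0 and 7 of 15 sex determination, 3 and 14 of 20 insulin and starvation, 1 and 16 of 28 neuropeptide, 0 and 3 of 4 transgene marker, 0 and 28 of 31 proteasome, 2 and 17 of 32 cuticle and 0 and 3 of 4 histone genes. Adjusted over the list alone, counts differed for core clock (0 and 8), neuron (0 and 7), sex determination (0 and 5) and proteasome genes (0 and 29). Heat shock genes went both ways, with Hsp70Bb at 0.77 and Hsp23 at -0.45, and the antiviral gene Vago had -0.65 and Dcr-2, an RNA interference nuclease gene, -0.18. The insulin-like peptide genes Ilp3 (-0.57) and Ilp2 (-0.92) and the neuropeptide gene Nplp2 (-0.66) fell. The JAK-STAT genes Stat92E (-0.34) and dome (-0.24) fell, as did Pdf (-0.36) and Pdfr (-0.28). Median and mean were negative while the test pointed up for the JAK-STAT, neuron, yolk, muscle, hemocyte and sex determination lists, while gut genes had a median of -0.14 and a mean of 0.06, and heat shock genes a median of -0.09 and a mean above 0, with tests that pointed up.

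By the limma test 6144 genes passed in males, 487 higher and 5657 lower, with 107 at least 2-fold higher and 82 at least 2-fold lower. The median log2 change was -0.16, and after median centring 3420 genes passed, 1549 higher and 1871 lower. On day 1 alone 6069 passed, 217 of them at least 2-fold lower, and on day 2 alone 3207, with 36 at least 2-fold lower.

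To see whether the effect was common to both sexes, the changes were compared across genes. Log2 changes had a Pearson correlation of 0.82 and a Spearman correlation of 0.44, and 85.1% had the same sign; genes are not independent replicates and the comparisons share no library. On centred values, without the shift of most genes that both sexes carry, 64.5% had the same sign (49.9% expected by chance). As deposited, 290 genes passed as higher in both sexes (22.9 expected by chance) and 3968 as lower (3150 expected), while 76 passed in opposite directions. Centred, 618 passed as higher in both (174 expected), 548 as lower (206 expected) and 130 in opposite directions (381 expected).

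**Figure D3:**
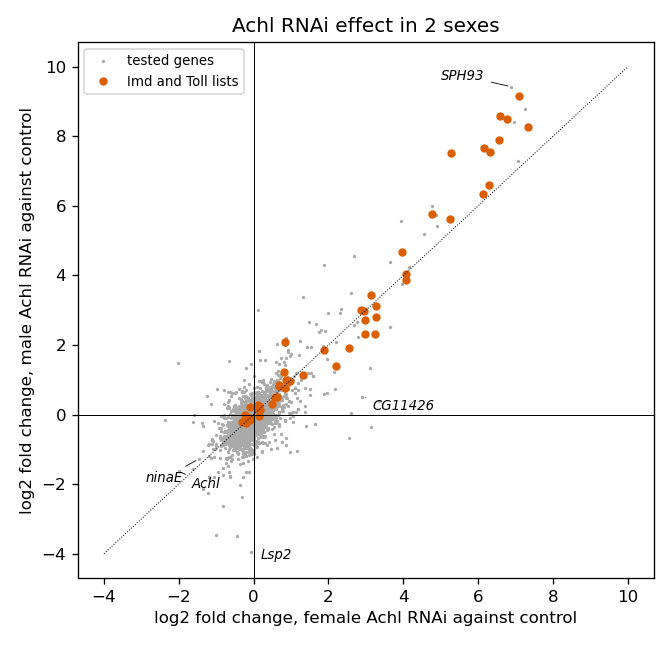
Log2 fold change of Achl RNAi against control in males against that in females, each point 1 tested gene, with Imd and Toll list genes in orange and the dotted line of equality. The Pearson correlation was 0.82, and SPH93 (9.43 in males, 6.88 in females), Lsp2 (-3.95 in males) and CG11426 lie off the line.

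The title of the series names sex-specific regulation, so the difference of the effects between sexes was tested itself. CG10073 rose in males by 3.01 from 0.703 ± 0.228 TPM and had a log2 change of 0.12, which did not pass, from 10.4 ± 3.54 TPM in females, a difference of -2.90 (SE 0.20, adjusted p = 5.3e-21). CG11426 rose in females by 2.91 (SE 0.16), from 26.4 to 215 ± 96.0 TPM, and in males from 19.9 ± 1.74 to 33.4 ± 23.3 TPM, a difference of 2.40 (SE 0.22). Spn88Eb, a serpin gene, rose from 22.9 to 267 TPM in males and from 41.9 to 121 TPM in females (-2.05). CG7227 had 62.7 and 59.6 TPM in females and rose from 5.83 to 18.3 TPM in males (-1.53). CG16995 fell from 6.58 to 0.203 TPM in males and from 1.16 to 0.209 TPM in females (1.83), and CG30091 rose from 1.21 to 7.45 TPM in males with 0.0175 and 0.148 TPM in females (-1.70). The RNAi values of CG16995 and the female values of CG30091 lie below the pseudocount of 1, so their differences depend on it. The male control mean of CG10073 also lies below it, so the size of that difference depends on the pseudocount too. By the limma test 1493 genes differed, 608 with the higher effect in females and 885 in males, against 1516 after centring (855 and 661), 1976 within high-mt libraries, 1693 on day 1 alone and 513 on day 2 alone (414 of them among the 1493).

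Lists for this difference passed camera and lost the call with an estimated correlation, in every case. Detoxification genes had 20 higher and 0 lower of 38 (21 and 3 adjusted over the list alone), adjusted p = 3.5e-11, and adjusted p = 0.216 with an estimated correlation, with Cyp12d1-p, Ugt86Dd (0.59) and Cyp12d1-d (1.04). Olfactory genes had 9 and 0 of 28 (10 and 0 adjusted over the list alone), adjusted p = 1.5e-08, and adjusted p = 0.216 with an estimated correlation, with Obp99b (3.04), Est-6 (0.49) and a5 (0.46). After centring both held with an estimated correlation, adjusted p = 0.00658 for detoxification and 0.013 for olfactory genes. Fat body genes had 5 and 0 of 14 (8 and 0 adjusted over the list alone), adjusted p = 2.1e-04, and adjusted p = 0.216 with an estimated correlation, with CG9914 (1.54) and Lsp2 (3.88). Ribosomal protein genes had 3 and 0 of 85 (2 and 0 adjusted over the list alone), and adjusted p = 0.828 with an estimated correlation, with RpS15Ab (0.29) and RpS27 (0.20). OXPHOS genes had 6 and 0 of 67 (5 and 0 adjusted over the list alone), and adjusted p = 0.768 with an estimated correlation, with ND-B14.7 (0.28) and COX7A (0.23). Neuron markers had 0 and 7 of 28 (0 and 11 adjusted over the list alone), and adjusted p = 0.635 with an estimated correlation, with ChAT, the acetylcholine synthesis gene (-0.40), and onecut (-0.23).

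Smaller numbers passed for the hemocyte list (2 and 0 of 13, both over all genes and adjusted over the list alone, adjusted p = 0.635 with an estimated correlation), led by Sr-CI, a scavenger receptor gene (0.29), and eater (0.39). Sex determination genes had 0 and 4 of 15 (0 and 4 adjusted over the list alone, adjusted p = 0.635 with an estimated correlation), with msl-2 (-0.19) and roX1 (-0.37). JAK-STAT genes had 1 and 0 of 9 (4 and 0 adjusted over the list alone, adjusted p = 0.635 with an estimated correlation), with Stat92E at 0.18, and proteasome genes 2 and 0 of 31 (0 and 0 adjusted over the list alone, adjusted p = 0.840 with an estimated correlation), with Prosalpha5 (0.23) and Rpn13 (0.37). Among lists that did not pass, mitochondrially encoded genes had 4 and 0 of 22 with a median of -0.34 and a mean of 0.31, and signs of median and mean also differed for Toll (0.02 and -0.06) and glia genes (-0.01 and 0.01). Core clock genes had 0 and 0 of 17 by limma.

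Female and male control heads were then compared, with positive values for higher levels in females. Yolk protein genes separated the sexes: Yp1 had 18431 ± 2886 TPM in females and 0.372 ± 1.32 in males, a log2 difference of 13.90 (SE 0.13), Yp2 11.85 and Yp3 9.69. The dosage compensation RNAs went the other way, roX2 with 0.542 ± 0.332 TPM in females and 211 ± 22.7 in males (-7.13, SE 0.08) and roX1 with 9.94 ± 1.42 and 1389 ± 101 TPM (-7.00, SE 0.07). The other female-high genes were CR40469 (9.02), CG32581 (7.22), CR45601 (7.00), which overlaps Yp1 on chromosome X, Obp99a (6.40), CG14529 (3.58), fit (3.45) and CG42586 (3.44). The other male-high genes were Obp99b (-4.45), Cyp4d21 (-4.20), Gnmt, a glycine methyltransferase gene (-4.11), the mitochondrial tRNA genes mt:tRNA:Leu-TAG (-3.77) and mt:tRNA:Arg-TCG (-3.10), Lsp2 (-3.50), CR42722 (-3.32) and the stress gene TotA (-2.72). CR42722 had a log2 difference of -0.76 and Lsp2 of -2.14 when the libraries of high mt:lrRNA alone were used.

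Ribosomal protein genes were higher in female heads, 83 of 85 with 0 lower (83 and 0 adjusted over the list alone), median 1.31, adjusted p = 2.3e-34, and adjusted p = 0.244 with an estimated correlation, with RpL37A at 1.31 and RpLP1 at 1.56. Neuron markers were lower, 27 of 28 (27 adjusted over the list alone), median -0.64, adjusted p = 1.5e-09, and adjusted p = 0.244 with an estimated correlation, with Gad1, the GABA synthesis gene, at -1.03 and Syx1A, a syntaxin gene, at -0.92. Glia markers had 1 higher and 14 lower of 18 (1 and 14 adjusted over the list alone), adjusted p = 0.00113, and adjusted p = 0.258 with an estimated correlation, with Gs2 at -0.69 and nrv2 at -0.85. Neuropeptide genes had 4 higher and 22 lower of 28 (4 and 22 adjusted over the list alone), adjusted p = 0.00783, and adjusted p = 0.244 with an estimated correlation, with Nplp1 at -0.83 and Dh31 at -0.78. Detoxification genes had 3 higher and 27 lower of 38 (3 and 27 adjusted over the list alone), adjusted p = 0.00146, and adjusted p = 0.792 with an estimated correlation, with Cyp4s3 at -1.74 and Ugt37b1 at -2.33. Proteasome genes had 22 higher and 0 lower of 31 (23 and 0 adjusted over the list alone), adjusted p = 0.00173, and adjusted p = 0.944 with an estimated correlation, with Rpt3 at 0.29 (0.11 within high mt:lrRNA) and Rpn5 at 0.23 (0.07 within it). Hemocyte markers had 7 higher and 2 lower of 13 (7 and 2 adjusted over the list alone), adjusted p = 0.0389, and adjusted p = 0.778 with an estimated correlation, with Ppn at 0.72 and Glt at 0.96. The yolk list had 4 higher and 2 lower of 7 (4 and 2 adjusted over the list alone), adjusted p = 0.0089, and adjusted p = 0.244 with an estimated correlation.

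The other lists did not pass between sexes. The mitochondrially encoded list had 0 higher and 16 lower of 22, median -0.97, adjusted p = 0.205, with mt:srRNA at -2.19 (-1.61 within high mt:lrRNA), and JAK-STAT genes had 1 higher and 7 lower of 9, with Socs36E at -0.53 and TotX at -2.41. Core clock genes had 1 higher and 10 lower of 17, led by sgg (-0.72) and slmb (-0.39). In the insulin list Thor, a translation repressor gene, was higher in females (1.22) and Sdr lower (-0.63). Sex determination genes had 2 higher and 7 lower of 15, a median above 0 and a mean of -0.96. Signs also differed for fat body genes (median 0.13, mean -0.07), insulin genes (-0.12 and 0.07), olfactory genes (-0.24 and a mean above 0) and histone genes (0.01 and -0.05). By the limma test 7209 genes differed, 2932 higher in females and 4277 lower, with 351 and 209 at least 2-fold. After median centring 7762 passed (3567 and 4195), within high mt:lrRNA libraries 6696 (1495 higher, 5201 lower), after rescaling over nuclear protein-coding genes 7260 (1916 and 5344), on day 1 alone 5906 (1434 and 4472) and on day 2 alone 8038 (4333 and 3705), so the share in each direction moved with the libraries and the scaling used.

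Circadian rhythms were tested in each group. The clock repressor gene vri had a peak-to-trough ratio of 1.91 at CT11.6 in female controls, 2.28 at CT12.8 in female RNAi, 2.50 at CT12.0 in male controls and 2.45 at CT12.3 in male RNAi. Clk, the clock activator gene, had 1.43 at CT23.2, 1.76 at CT23.8, 1.58 at CT22.3 and 1.67 at CT22.7 in the same order. The negative regulator genes per and tim were called in 3 groups and missed the threshold in female controls, where per had 1.55 at CT10.3 (adjusted p = 0.136) and tim 1.40 at CT12.9 (adjusted p = 0.0637). In the other groups, in that order, per had 1.89 at CT13.0, 1.92 at CT10.4 and 2.04 at CT11.9, and tim 1.55 at CT14.4, 1.79 at CT14.8 and 2.02 at CT15.1. Pdp1, a clock activator gene, was called in all 4 groups, with peaks at CT12.3, CT13.9, CT12.7 and CT12.3 in the same order and ratios of 1.52 in male controls and 1.58 in male RNAi. The fitted peaks of these 5 genes were all later in female RNAi than in female controls, unlike the median of the rhythmic genes below. Of 17 core clock genes 3 were called in female controls and 5 in each of the other groups, and no clock gene passed the test of a rhythm difference, the lowest adjusted p in females being 0.739, for per. A p above the threshold does not show that peak times were equal. In level, per had log2 changes with RNAi of -0.20 in females (adjusted p = 0.0505) and -0.32 in males, tim -0.30 and -0.36, and cry -0.22 and -0.56. The median gene moved by -0.18 in females and -0.16 in males, so per and cry in females lay close to the shift of most genes.

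**Figure D4:**
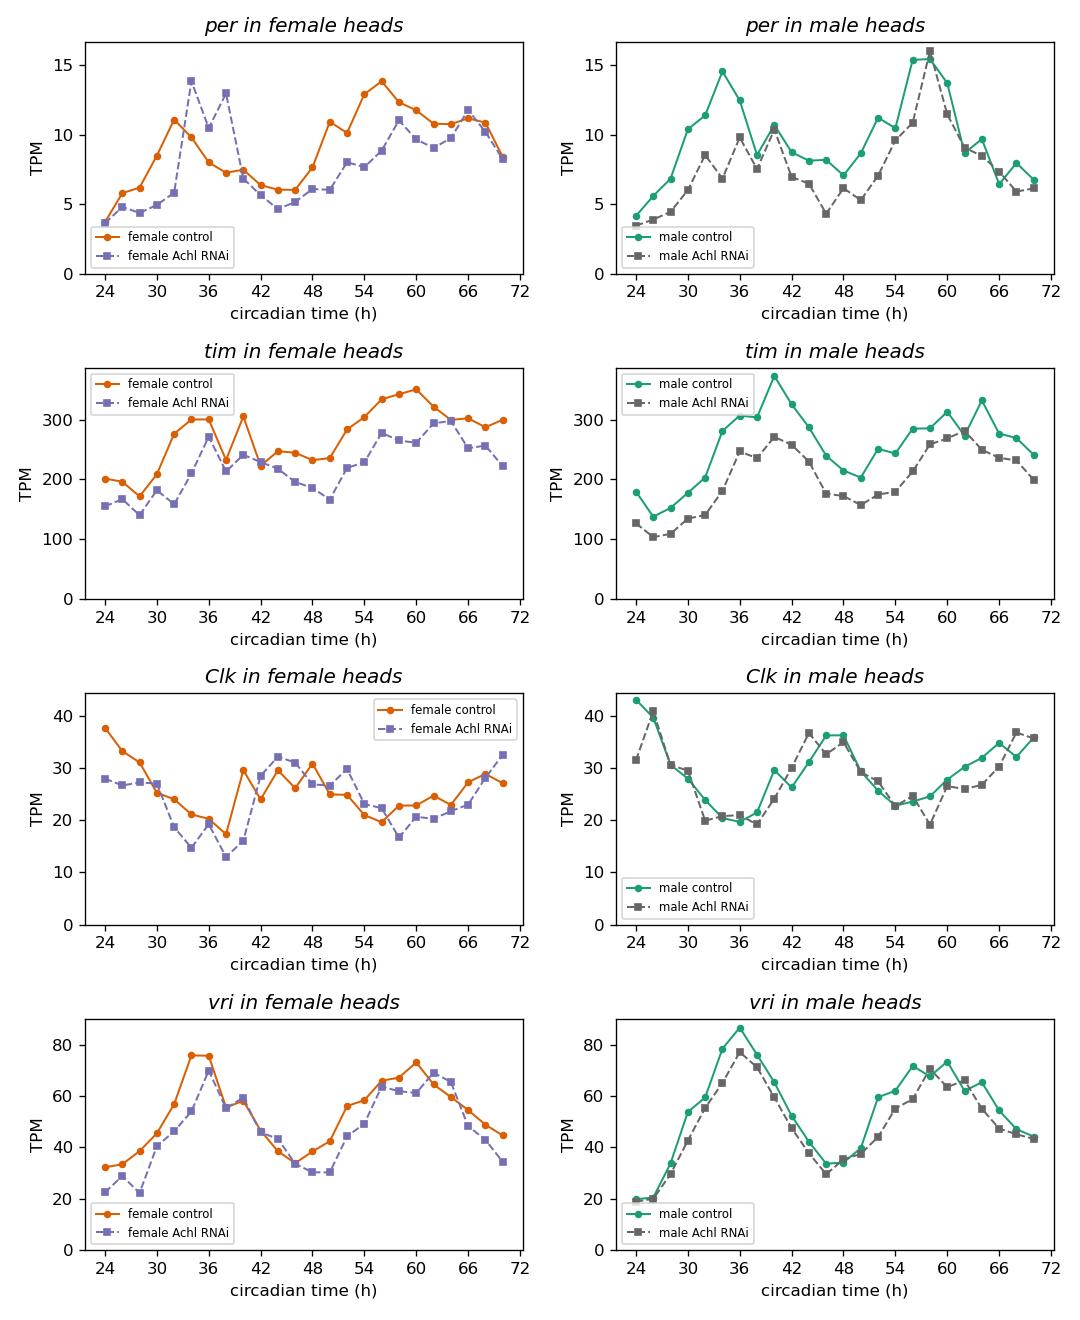
TPM of per, tim, Clk and vri against circadian time in hours, in female (left) and male (right) heads, each point 1 library of control (circles) or Achl RNAi (squares). vri peaked between CT11.6 and CT12.8 and Clk between CT22.3 and CT23.8 in the 4 groups.

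Beyond the clock, the genes of lowest p in each group were these. Ugt35b, a glucuronosyltransferase gene, had a ratio of 2.35 at CT2.25 in female controls and 2.34 at CT1.51 in female RNAi, and CG33965 had 3.82 at CT21.2 in female controls and 5.68 in male controls. Other leading genes in female controls were GstZ2 (2.95 at CT3.42), gol (2.11 at CT8.61), Usp8 (2.74 at CT8.47) and CG11407 (2.20). In female RNAi they were CG11891 (3.26 at CT23.5), CG34180 (3.57 at CT23.2), CG33965, Cyp4d21 (3.23 at CT21.5) and CG11796 (2.59 at CT1.76). In males gol, Ugt35b, CG33965, Usp8, to and Jhe, a juvenile hormone esterase gene, led in both genotypes, with Jhe at 3.96 in controls and 3.71 in RNAi and to at 2.42 and 2.29. Clock-controlled outputs were rhythmic in 13, 9, 11 and 9 of 23 genes in female control, female RNAi, male control and male RNAi heads.

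The F test called 169 rhythmic genes in female controls, 148 in female RNAi, 133 in male controls and 108 in male RNAi (974, 1138, 596 and 1594 at an unadjusted p under 0.05). With each group fitted alone the counts were 121, 32, 216 and 154 in the same order, and by the rank test 107, 28, 202 and 116. Both put each male group above the female group of its genotype, so the order of the sexes depends on the spread shared in the joint fit. Female groups shared 61 called genes (2.37 expected), male groups 71 (1.36 expected) and control sexes 76 (2.13 expected), and 33 genes were called in all 4 groups. These expected counts take the groups as independent. Peaks of shared genes lay within 2 h in 77.0%, 83.1% and 85.5%, and the median shift in RNAi against control was -0.41 h (earlier) in females and 0.26 h in males. Within low-mt libraries 46 genes were called in female controls and 149 in female RNAi, and within high-mt libraries 244 and 81, so the female counts move with the set of libraries used.

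Whether RNAi changed rhythms was tested directly in females. The ubiquitin ligase gene gol peaked at CT8.61 (SE 0.42 h) in controls and CT12.3 (SE 0.52 h) in RNAi, with ratios of 2.11 and 1.82 (adjusted p = 0.0177). Hph, a prolyl hydroxylase gene, peaked at CT2.59 in controls and at CT15.5 in RNAi (ratio 1.26), adjusted p = 0.0303, and its rhythm in RNAi was not called (adjusted p = 0.123). The next genes did not pass: Slob, with peaks at CT7.27 and CT12.5 (adjusted p = 0.051), Usp8, with CT8.47 and CT11.9 (0.0828), CG8550 (0.0828) and Gp210, a nuclear pore gene, with CT9.35 and CT13.5 and ratios of 1.67 and 1.24 (0.0828). Limma called 2 genes over all tested genes (786 at an unadjusted p under 0.05), and 88 of the 256 genes rhythmic in either female group, a set picked by rhythm in these same libraries. Centring gave 9 called genes, of which 1 was among the 2 above, high-mt libraries alone gave 141, with 1 of the 2, and low-mt libraries gave 2 genes, with neither gol nor Hph, so the count and the calls are not stable.

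**Figure D5:**
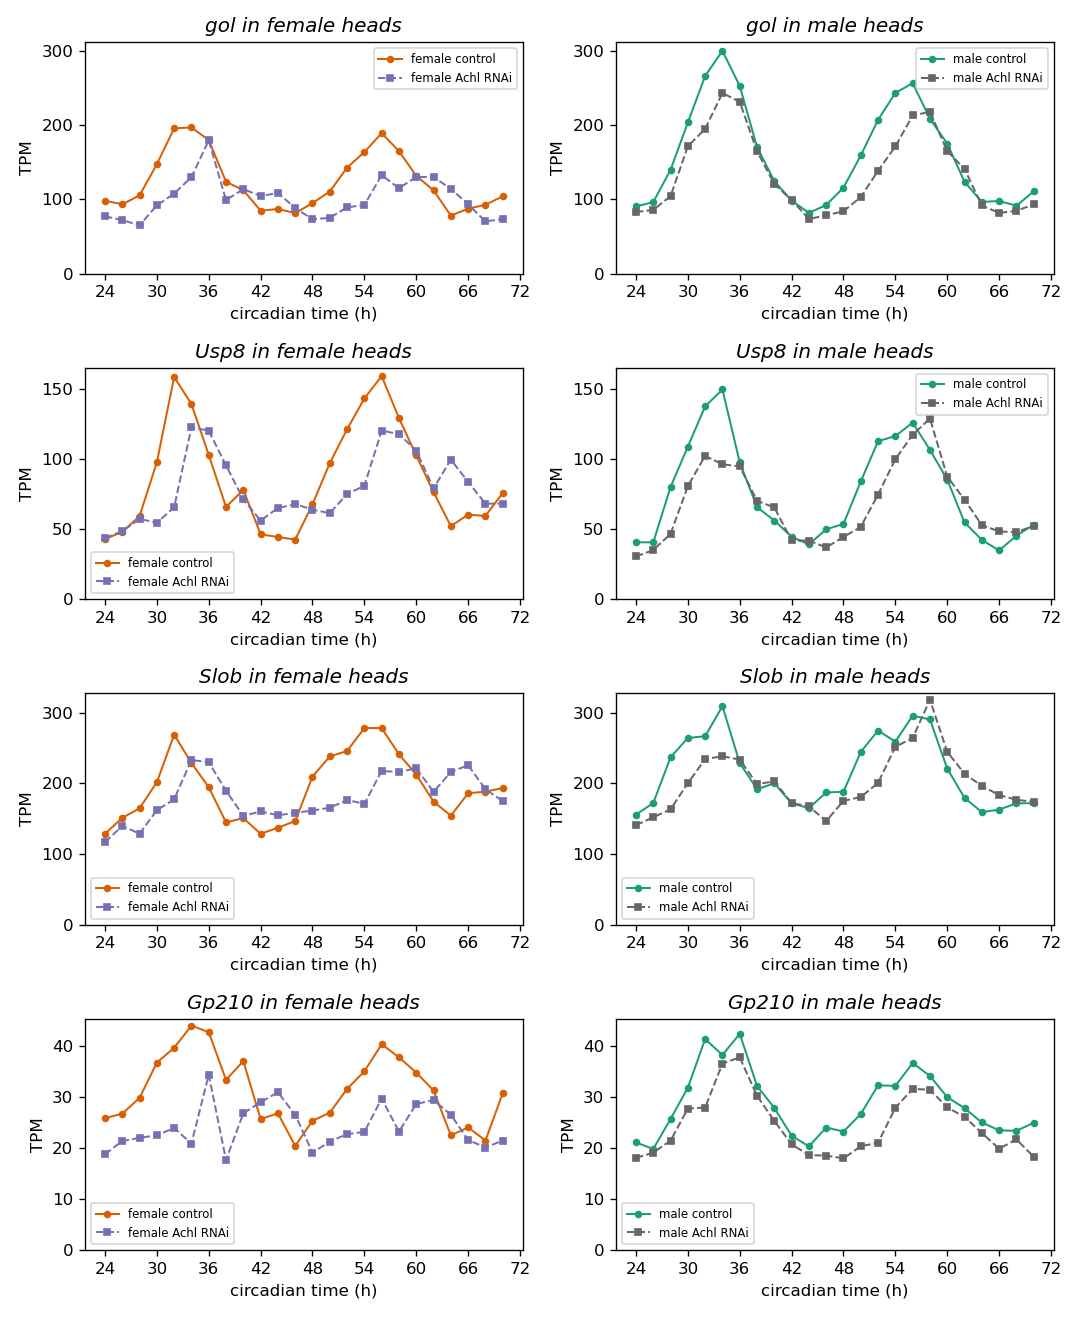
TPM of gol, Usp8, Slob and Gp210 against circadian time in hours, in female (left) and male (right) heads, each point 1 library of control (circles) or Achl RNAi (squares). Peaks of gol lay at CT8.61 in female controls and CT12.3 in female RNAi, and at CT8.53 and CT9.61 in males, where the difference did not pass.

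In males no rhythm difference passed. The genes of lowest p were CR14033 (adjusted p = 0.421), CG8046, CG5359, CR45405, CG9531 and Achl itself (adjusted p = 0.968 for each of the last 5). Peaks of gol were at CT8.53 and CT9.61, of Usp8 at CT7.95 and CT9.80 and of Slob at CT7.67 and CT10.3 in control and RNAi heads. Limma called 0 genes, with 200 at an unadjusted p under 0.05, and 1 of the 170 genes rhythmic in either male group. The test that the rhythm change itself differed between sexes gave 0 genes with limma, with 383 at an unadjusted p under 0.05, and gol had p = 0.0523 there before adjustment.

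Between the sexes in controls 1 gene passed by limma (285 at an unadjusted p under 0.05, and 22 of the 226 genes rhythmic in either). It was rost, a muscle fusion gene, with a ratio of 1.44 at CT9.82 in females and 1.72 at CT2.01 in males (adjusted p = 0.0336). The next genes were Fmo-2 and CR44390 (adjusted p = 0.0584 for each), TpnC4, a troponin gene with a ratio of 3.53 at CT9.25 in males (0.355), Rgk2 and CG8353 (0.435 for each). The call of rost was lost after centring, without the low filter, on each day alone, after nuclear rescaling and within high mt:lrRNA libraries.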

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

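The tests of nuclear rescaling, of leaving out the Imd and Toll lists, of dissected tissue, of infected pools and of a linked arm were chosen only after the results were seen, and the tests of infected pools by the second-highest control and by all Imd genes were added after the first had come out the other way.

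Most genes had lower TPM in Achl RNAi heads, with a median log2 change of -0.18 in females and -0.16 in males. Imd and Toll list genes held 6.81% of TPM in female RNAi against 0.827% in controls, and 7.09% against 0.856% in males, and leaving them out and rescaling moved the median to -0.0989 (SE 0.0275) and -0.0740 (SE 0.0225), between the bounds set. Leaving out the 50 genes of largest rise moved it to -0.0211 in females, where 1858 genes then passed (1001 higher, 857 lower), and to 0.0495 in males, where 4263 did (3062 higher, 1201 lower), but leaving out genes chosen for their rise can only raise it. Rescaling over nuclear protein-coding genes left the median at -0.16 in females and -0.13 in males, so mitochondrial and ribosomal RNA do not account for it. How much of the shift comes from the TPM scale and how much from a fall of many genes stays open.

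The antimicrobial peptide genes rose in both sexes, and several causes other than loss of Achl were weighed. Fat body and hemocyte markers had a highest median of 0.0481, below the rise that extra tissue would need. Of the 71 genes at least 2-fold higher in both sexes 53.5% lay on chromosome 2R, which carries Achl and 20.6% of tested genes, while others, such as CecA1 (3R) and Drs (3L), lay on other arms, so their positions do not follow 1 linked region, but an effect of a linked variant on genes elsewhere was not tested and stays open. By the mean of 19 Imd genes, picked as called higher in both sexes, 21 of 48 RNAi libraries lay above the highest control library (female, CT56, 7.77). This fitted the test for a few infected pools, but that bound rests on 1 control library, and 46 lay above the second-highest (5.65). By all 25 tested Imd genes 19 lay above the highest, 46 above the second-highest and 48 above the third-highest. With all 48 RNAi libraries above the third-highest control, these values argue against an infection of only a few RNAi pools. An infection, a genetic background or a transgene effect shared by the whole RNAi stock could give the same pattern and was not separable from genotype here.

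The level differences exceeded those of chance groupings of the same libraries. Of 100 groupings with labels swapped within CT, the real one included, 1 reached the real count for RNAi in females (6382, highest other 5298), 1 in males (6144, highest other 4181), 1 for sex in controls (7209, highest other 4947) and 1 for the interaction (1493, highest other 246). Only the real grouping reached each count, and 1 of 100 is the lowest share that this number of groupings can give.

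Effects of Achl RNAi differed between sexes in 1493 genes, the count that marks the genes below. CG10073 differed by -2.90 (0.12 in females, 3.01 in males), CG7227 by -1.53 (-0.07 and 1.46), CG30091 by -1.70 (0.14 and 1.84) and Spn88Eb by -2.05 (1.32 and 3.38). CG11426 differed by 2.40 (2.91 and 0.51) and CG16995 by 1.83 (-0.81 and -2.64). The differences of CG16995 and CG30091 rest on values below the pseudocount of 1, and CG16995 fell to nearly the same level in both sexes. Male control means of CG10073 and of SPH93, given below, also lay under that pseudocount, so the sizes of their differences depend on it. Among genes that fell in males, CG16926 differed by 2.45 (-1.02 and -3.47), squ by 1.65 (-0.36 and -2.01), Obp99b by 3.04 (-0.45 and -3.49), CG10621 by 1.51 (-0.28 and -1.79), tobi by 2.05 (-0.32 and -2.37), Lsp2 by 3.88 (-0.07 and -3.95) and CG33926 by 1.06 (-1.21 and -2.27). CG9377 differed by -1.78 (-1.25 and 0.53), CNMa by -1.05 (-1.36 and -0.32), CG5160 by -0.36 (-1.22 and -0.87) and CG11200 by -0.35 (-1.20 and -0.85). SPH93 differed by -2.55 (6.88 and 9.43), DptB by -1.98 (6.59 and 8.57) and DptA by -2.07 (7.09 and 9.16). In RNAi heads DptA and DptB were higher in females (3559 and 4628 TPM) than in males (2768 and 2613 TPM). Their larger change in males thus rests on lower control values, with a median DptA of 9.55 TPM in female and 0.88 in male controls. The male value is below the pseudocount of 1.

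Lists with a difference between sexes had these medians: detoxification 0.25, olfactory 0.24, fat body 0.25, ribosomal protein 0.20, OXPHOS 0.19, JAK-STAT 0.18, hemocyte 0.17, proteasome 0.10, neuron -0.17 and sex determination genes -0.0677, and every one lost its call with an estimated correlation (adjusted p from 0.216 to 0.840), while on centred values detoxification and olfactory genes kept it (0.00658 and 0.013).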

How the results depend on the processing

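The settings with nuclear rescaling, mt:lrRNA and centred list tests were added only after the results were seen, and the cause of a moved count was not tested. For male rhythm counts in the mt:lrRNA settings it follows from the design, as given below. Limits are the single library per time point, the overlap of mt:lrRNA class with day in females and the unknown control construct. Count-based tests were not applied because the values are TPM. Of 2770 values for levels of named genes 2724 kept their call and 46 were weaker. For rhythms 1366 of 1426 kept it, 28 were weaker and 32 stronger, and for rhythm differences 228 of 281, with 15 weaker and 38 stronger. No level value changed sign, though many of these genes were picked for their call and direction in these same libraries. For rhythms and rhythm differences only the call was compared, so a moved peak would not show.

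Median centring gave 2351 genes for RNAi in females and 3420 in males, of which 1666 and 2384 were among the 6382 and 6144 called as deposited, 9 rhythm differences in females and 0 between sexes. Limma without trend and robust options gave 2 rhythm differences between sexes, and no low filter gave 0. On day 1 rhythmic genes numbered 84 in female controls, 77 in male controls and 2464 in male RNAi, with 11 rhythm differences in females and 1 in males. On day 2 RNAi in males gave 3207 genes and the interaction 513, with 102 rhythmic genes in female controls and 3053 in female RNAi, and 96 rhythm differences in females and 4 in males. A linear trend gave 618 rhythmic genes in female controls and 294 in female RNAi, 12 differences in females and 5 between sexes. A 12 h harmonic gave 4 differences in females. With only the groups compared, rhythmic genes numbered 32 in female RNAi and 216 in male controls, with 2 differences between sexes.

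In the order female control, female RNAi, male control and male RNAi, rhythmic genes numbered 104, 76, 78 and 62 at adjusted p under 0.01, 90, 77, 79 and 67 at a ratio of at least 1.5, and 84, 75, 69 and 61 with a period of 20 h. A period of 28 h gave 50, 117, 62 and 26. The rank test gave 107 in female controls, 28 in female RNAi and 202 in male controls. Among genes rhythmic in either group, 88 differed in females, 1 in males and 22 between sexes, a choice of genes that is not independent.

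Nuclear rescaling gave 0 rhythm differences between sexes. The mt:lrRNA class as a term gave 324 rhythmic genes in female controls, 282 in female RNAi and 668 in male RNAi, with 4 differences in females. Together with centring it gave 3018 genes for RNAi in females, 477 rhythmic in female controls, 209 in male controls and 539 in male RNAi, 11 differences in females and 3 between sexes. High mt:lrRNA libraries gave 81 rhythmic genes in female RNAi and 281 in male RNAi, 141 differences in females and 0 between sexes, and low ones 46 rhythmic genes in female controls. No male library was below 50000 TPM, so neither the class term nor the use of high libraries alone changed a fitted male course. These steps moved male counts only through the spread estimate that the groups share. Without 5 first-day female libraries of low mt:lrRNA there were 8 differences in females and 2 between sexes. CT as a block gave 6780, 6413, 1667 and 7424 genes for RNAi in females, in males, the interaction and sex. The same-CT correlation of residuals had a mean of 0.21 in females (lowest -0.35) and 0.11 in males (lowest -0.22).

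Gene list tests that passed numbered 35, and 4 with an estimated correlation, 10 with centring and an estimated correlation, 36 with centring and 34 with CT as a block. The correlation of effects between sexes was 0.82 over all genes, 0.84 over genes called in either sex and 0.88 over genes above the median level.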

Other observations

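The values by chromosome, for single control libraries, for a 16 h course and for the overlap of class and course were looked at only after the results were seen, while the tests of a 48 h course and of random orders were written before.

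Chromosome 4 genes were lower in female than in male control heads. Of 99 tested genes 84 were lower and 4 higher in females, with a median log2 difference of -0.57 (SD 0.355), while the medians of the other arms lay between -0.08 and -0.01. The chromosome 4 median was -0.55 after centring, -0.75 after rescaling over nuclear protein-coding genes and -0.40 within libraries of high mt:lrRNA, and those of the other arms then lay between -0.05 and 0.01, -0.21 and -0.16, and -0.21 and -0.15, so the gap was smaller within high mt:lrRNA libraries.

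Peak times of called genes were counted in bins of 4 h and not compared by a test. In female RNAi 67 rhythmic genes (45.3%) peaked from CT20 to CT24 and 2 from CT8 to CT12, while in female controls 55 (32.5%) peaked from CT0 to CT4 and 25 from CT8 to CT12. These are mostly different genes: 61 were called in both female groups, and their median shift was only -0.41 h. Chance was also not excluded for the count in female RNAi, as given below. In male controls 40 genes (30.1%) peaked from CT0 to CT4, and in male RNAi 31 (28.7%) from CT16 to CT20. By list, rhythmic detoxification genes numbered 2 in female controls, 4 in female RNAi, 5 in male controls and 1 in male RNAi, and photoreceptor genes 4, 2, 3 and 1. Imd genes numbered 1, 0, 0 and 0, and Toll, ribosomal protein and neuropeptide genes 0 in every group.

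Some control libraries had raised Imd genes. DptA had 3335 TPM in the female control at CT56, 814 at CT24 and 264 at CT68, and 422 in the male control at CT54, against a median of 0.88 TPM in male controls.

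Many genes followed a 48 h course in females: 4497 in female controls and 4085 in female RNAi, with 6 in male controls and 2194 in male RNAi. A 16 h course was called in 2592 genes of female RNAi and in 0 of each other group. Female libraries of low mt:lrRNA fell mostly on the second day, and between low and high libraries 7075 genes differed in female controls and 6323 in female RNAi. With the mt:lrRNA class as a term, 1 gene kept a 48 h course in female controls, while 1333 did in female RNAi, a value that could not tell. The class overlaps with the day, and the 48 h course takes up 50.5% of its variance in female controls, so a batch of libraries by day and a real drift over the days stay open. A new set of libraries with days spread over batches would separate them. The male RNAi genes followed the course with no library of low mt:lrRNA. In that group mt:lrRNA still varied, from 95959 to 194668 TPM on day 1 and from 92193 to 136332 TPM on day 2. Whether the male RNAi course follows these values was not tested.

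Rhythm counts were compared with 100 random orders of the CTs or groupings, the real one included. In male controls 1 reached the real count (133, highest other 23) and in male RNAi 1 (108, highest other 10), the lowest share that 100 orders can give. In female controls 3 did (169, highest other 616) and in female RNAi 14 (148, highest other 5949), so chance cannot be excluded for the count in female RNAi, and counts several times the real one point to a structure of the samples. This concerns the count and not each gene: 61 of the 148 were also called in female controls (2.37 expected if the groups were independent) and 33 in all 4 groups, and vri passed in female RNAi at adjusted p = 5.4e-09. Residuals of the female groups at the same CT had a mean correlation of 0.21, so a structure shared by both groups can add to that overlap. For rhythm differences 3 groupings reached the real count in females (2, highest other 4), 100 in males (0, highest other 1) and 4 between sexes (1, highest other 10).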
